A study of Mus musculus with 2 samples.

How the data were processed

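mRNA sequencing libraries from mouse bone marrow derived macrophages were compared, 1 mock and 1 infected with HSV-1 for 6 h, with the groups taken from the labels. Per the submitters' processing notes, the authors used CASAVA 1.8 and HISAT2 with the GRCm38 (mm10) genome build. The read counter, the annotation release, the strandedness of the counting, the normalization tool and the gene filter were not given in the sources used here.

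The deposited values are a normalized signal per gene, not raw counts. In each library 100% of the values were whole multiples of the same step, within 0.001 reads, so each value was divided by that step to recover whole reads. Taken as read counts divided by a size factor per library, the deposited values had factors of 1.16 (mock) and 0.927 (infected). Their product was 1.08, where median-of-ratios factors computed on these libraries alone multiply to 1, and 119 of the 13883 genes had 0 reads in both libraries. The design written before the data were examined assumed raw counts, and it was applied unchanged to the recovered reads. A count test could not be fitted, because each group had 1 library.

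The recovered reads totalled 21861449 (mock) and 26807478 (infected), with 591 and 671 genes at 0 reads. They were scaled by TMM effective library sizes from edgeR 4.0.16 in R 4.3.3, which were 27084820 and 21637593. A gene was assessed when the mean of its scaled CPM values was at least 1. The fewest reads behind an assessed gene, over both libraries, were 44. A gene was higher when its ratio was at least 2 and its 95% exact conditional binomial (Clopper-Pearson) interval lay above 1, and lower when its ratio was at most 0.5 and the interval lay below 1. A library with 0 reads was given a floor of 3 reads for the ratio. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. The rule was tested on simulated data with 200 changed genes, for the comparison of infected against mock. It called 50 of 50 genes at each of 3-fold higher, 3-fold lower, 8-fold higher and 8-fold lower, and 8 of 10492 unchanged genes (0.0762%). Both simulated libraries were drawn with counting error alone around shared gene means, and the changes were balanced between higher and lower. The rates therefore do not measure false calls from variation between cultures or from scaling.

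Gene symbols and GRCm38 coordinates came from GENCODE M21. Of the deposited identifiers, 13875 matched without the version suffix and 11846 with it. The 40 gene lists of pathways, cell types and responses, the size rule and the rule for named genes were fixed before the data were examined. That rule took the 12 largest and 12 smallest ratios among called genes with a mean of at least 10 CPM, leaving out unnamed gene models, which were 18 of 1457 higher and 9 of 703 lower genes. It also took the 3 assessed members of each list with the largest absolute log2 ratio and the most abundant member, the 5 most abundant genes of each library, and Ifnb1, Cxcl10, Isg15, Tnf, Il6, Il1b, Csf1r, Actb and Gapdh. Of the 152 genes it gave, 62 overlap another annotated gene, and reads of near-identical paralogs are reported as uncertain.

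A list's median log2 ratio was given with a 95% order-statistic interval and its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins. Matching on mock expression was an alternative. Shares of reads were computed over all genes of a library. The alternatives were scaling by total reads, totals without the 10 most abundant genes, DESeq2 1.42.0 size factors, no expression minimum, a minimum of 5 CPM, a pseudocount of 1 CPM, the deeper library thinned to the depth of the other, a ratio of 4, and a whole interval past 2-fold. The deposited size factors, and the calls without stromal genes, were added after the data were seen. Trends with GC content and with length of the longest transcript were removed by a lowess fit (span 0.3) in statsmodels 0.14.6, and other computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Viral transcripts were not analysed here, and the values of some list members are not reported here.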

Results

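Gene expression was measured by mRNA sequencing in bone marrow derived macrophages from C57BL/6 mice aged 10 weeks. Marrow cells had been grown for 7 days with GM-CSF, a growth factor for myeloid cells, and were then replated. The mock library was untreated (0 h of infection), and the infected library was taken after 6 h with strain 17 of herpes simplex virus 1 (HSV-1), a DNA virus. No mock library labelled as harvested at 6 h was used here. Each condition had 1 library, so no difference reported here has a replicate check and no p-value was computed. Reads on 13883 mouse genes came to 21861449 in the mock library and 26807478 in the infected library. The 10 most abundant genes held 17.7% of the mock reads and 12.1% of the infected reads. Ratios are infected over mock after TMM scaling, and their 95% intervals are exact for the reads and cover counting error only. Intervals of list medians are instead order-statistic intervals over the member genes, which are not independent replicates. Those intervals and the list percentiles describe these libraries and are not tests of infection. A gene was assessed at a mean of at least 1 CPM (scaled counts per 1000000 reads), and was higher or lower at a ratio of at least 2 in that direction with an interval excluding 1. Members named only because they make up a count of 5 or fewer were chosen after their values were seen.

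The comparison asked how the macrophage transcriptome differed after 6 h of HSV-1 infection. The infected library held far more RNA for cytokines, interferon beta and interferon-induced antiviral proteins. Il12a, a subunit of interleukin 12, had 1 mock and 2866 infected reads, a ratio of 3588 (95% interval 643 to 1.42e+05). Il6, an inflammatory cytokine, had 7 and 19289 reads, a ratio of 3449 (1674 to 8580). Nos2, the inducible nitric oxide synthase, was 743-fold higher (532 to 1074), and Ptgs2, the inducible cyclooxygenase, was 389-fold higher (340.4 to 448). Col1a1, a chain of type I collagen, was among the 12 smallest ratios at a mean of at least 10 CPM, and it had 5730 mock and 8 infected reads and was 572-fold lower (290.2 to 1326).

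Of 10703 assessed genes, 1868 (17.5%) were higher in the infected library, 1759 (16.4%) were lower and 7076 were neither. At least 10-fold differences were found for 395 higher and 161 lower genes, and at least 100-fold differences for 66 higher and 22 lower genes. The higher genes held 12.7% of mock reads and 42.8% of infected reads, and the lower genes held 7.13% and 1.55%. The median log2 ratio of all assessed genes was -0.02, a value that TMM scaling itself brings near 0, and it was -0.64 with scaling by total reads. List counts below use TMM, and several are also given by total reads. With the libraries scaled by total reads in place of TMM, every log2 ratio dropped by 0.62, and higher genes made up 22.4% of the calls in place of 51.5%.

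**Figure D1:**
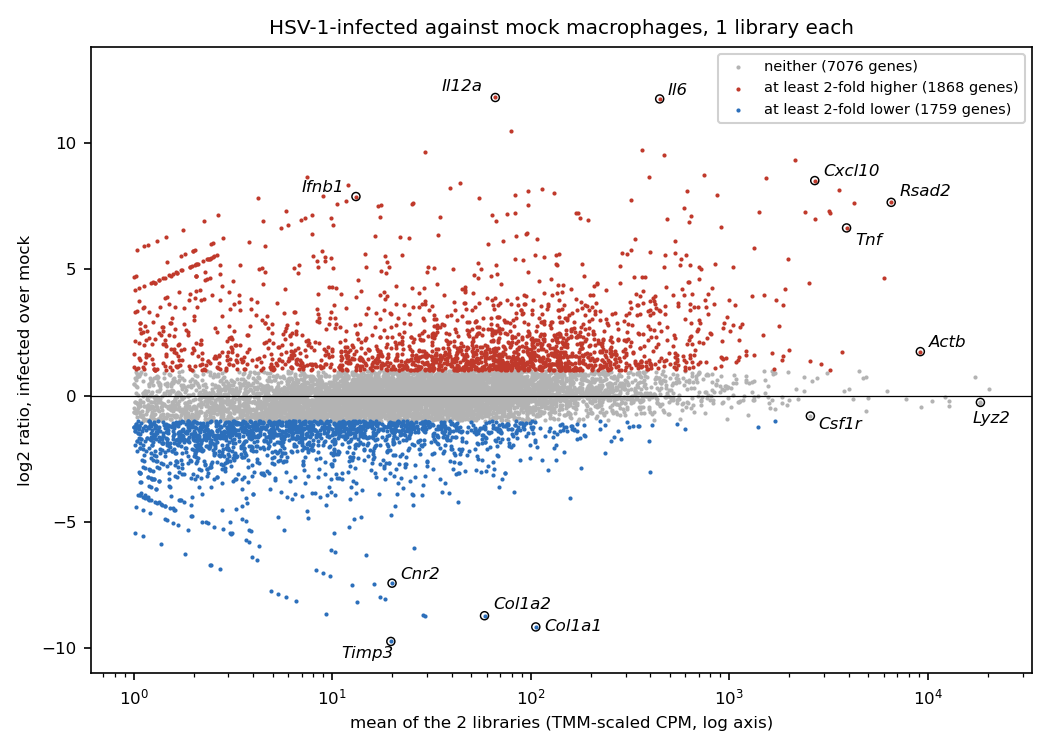
Each point is 1 of the 10703 assessed genes, with its mean TMM-scaled CPM on a log axis and its log2 ratio of the infected to the mock library. The 1868 higher genes reach log2 ratios of 11.81 (Il12a) and 11.75 (Il6) and include abundant genes such as Rsad2, while the lowest point is Timp3 at -9.74.

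The other genes with the largest ratios among those of at least 10 CPM were Edn1 (endothelin 1, 1439-fold), Il27 (859-fold), the transcription factor Lhx2 (797-fold), Il1a (640.1-fold), the activation marker Cd69 (427-fold), Tnfsf15 (403-fold), the chemokine Cxcl10 (367-fold, 332 to 406) and Serpina3g (339-fold). Serpina3g has near-identical copies, so its share of reads is uncertain. Among the smallest ratios, Timp3, a metalloproteinase inhibitor, had 1067 mock reads and 1 infected read (852-fold lower, 153 to 33699). Sparc, Col1a2, Bgn, Hspg2 and Aebp1 had log2 ratios of -8.73, -8.72, -8.68, -8.16 and -7.44. Col5a2, Col12a1 and the collagen chaperone Serpinh1 had 0 infected reads. Against a floor of 3 reads they were 265-fold, 251-fold and 182-fold lower, with lower 95% limits of 215, 203 and 148. Ccn2, a matrix-associated growth regulator, was 79.1-fold lower (39.9 to 184). Cnr2, the cannabinoid receptor of immune cells, had 1077 mock and 5 infected reads (172-fold lower, 73.5 to 531). On GRCm38, Il6 (ENSMUSG00000025746.11) lies at 30013114 to 30019981 on chromosome 5, Cxcl10 (ENSMUSG00000034855.13) at 92346638 to 92348889 on chromosome 5, Col1a1 (ENSMUSG00000001506.10) at 94936224 to 94953042 on chromosome 11 and Cnr2 (ENSMUSG00000062585.11) at 135895394 to 135920207 on chromosome 4. The annotated Cxcl10 locus overlaps Art3 and the Timp3 locus lies within Syn3. Strandedness of the counting was not given, so reads of such pairs were not separable.

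**Figure D2:**
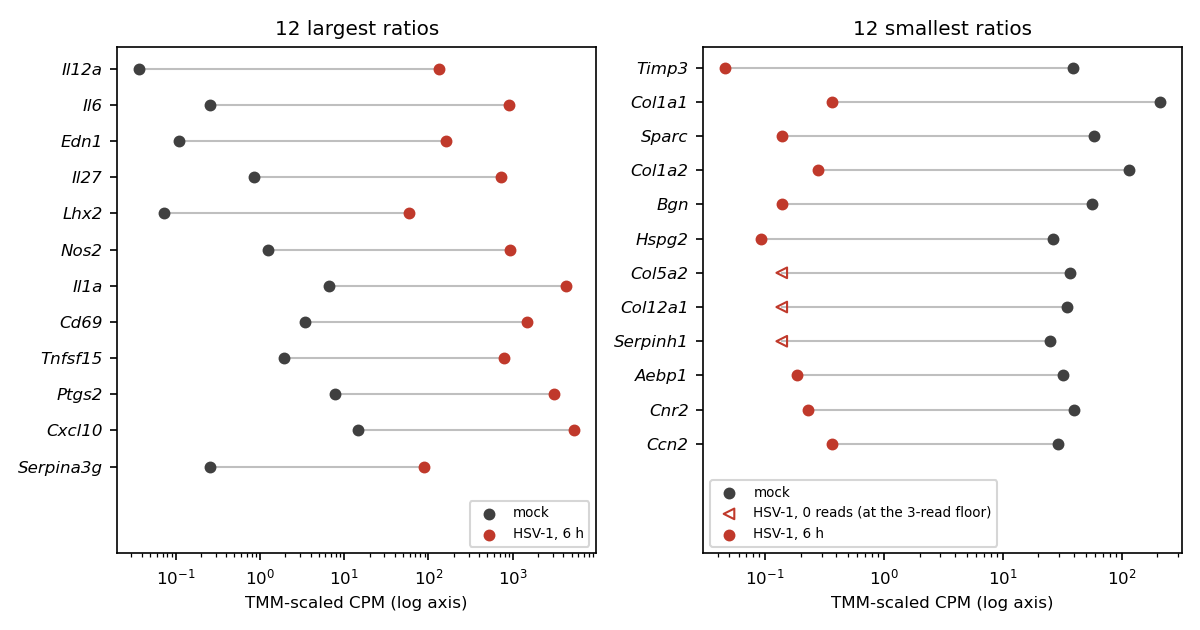
TMM-scaled CPM on a log axis in the mock (dark) and infected (red) libraries for the 12 genes with the largest ratios and the 12 with the smallest, among genes of at least 10 CPM on average. Open triangles mark Col5a2, Col12a1 and Serpinh1, which had 0 infected reads and are drawn at the floor of 3 reads, while Il1a and Cxcl10 were the most abundant in the infected library among the largest ratios.

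Interferon beta and every assessed antiviral gene were higher in the infected library. Ifnb1, which encodes interferon beta, had 3 mock and 567 infected reads, a ratio of 237 (80.5 to 1151). It was the only one of 16 measured interferon genes to reach the expression minimum. The others had 0 mock reads, and at most 24 infected reads, in Ifna2, whose near-identical family copies leave the assignment uncertain. All 58 assessed interferon-stimulated antiviral genes were higher, with a median log2 ratio of 4.12 (95% interval 3.78 to 5.14). With scaling by total reads, 55 of the 58 were still higher. Rsad2, the antiviral enzyme viperin, had 1747 mock and 281527 infected reads, a ratio of 202 (192 to 212). Isg15, a ubiquitin-like modifier, was 51.9-fold higher (47.1 to 57.4), and the GTPase gene Iigp1 was 294-fold higher (192 to 475). These antiviral genes held 0.441% of mock reads and 6.47% of infected reads. Their median lay at the percentile of 100 among 10000 random lists matched on mean expression.

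Inflammatory cytokines and chemokines followed the same direction. Among 21 assessed cytokine genes, 20 were higher, with a median log2 ratio of 6.02 and a percentile of 100. By total reads 17 of 20 were higher, with a median of 5.51, and with a pseudocount of 1 CPM the median was 4.23. Tnf had 2091 mock and 166935 infected reads, a ratio of 99.9 (95.7 to 104), and Il1b, whose locus overlaps the antisense gene Il1bos, had a ratio of 126 (119 to 134). Osm, with a log2 ratio of 0.67, was the cytokine that was neither higher nor lower. Of 17 chemokine genes, 13 were higher, with a median log2 ratio of 6.26 that was 4.84 with the pseudocount. Ccl3 was 287-fold higher (266 to 310.0) and Ccl4 was 244-fold higher (212 to 283). The remaining chemokines, Pf4, Ccl6, Cx3cl1 and Cxcl16, had log2 ratios of -0.32, -0.28, 0.44 and 0.64, of which that of Cx3cl1 was negative with scaling by total reads. The cytokines together held 0.0348% of mock reads and 1.81% of infected reads, and the chemokines 0.181% and 2.14%.

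Signalling and early-response genes were higher in part, to an extent that depended on the scaling. Of 28 NF-kB feedback and target genes, 26 were higher, with a median log2 ratio of 2.40, Nfkbiz at 5.08 and the abundant Tnfaip2 3.49-fold higher, and Bcl3 (0.11) and Relb (0.58) were neither. With scaling by total reads, 21 of the 28 were higher. Of 21 interferon receptor and JAK-STAT genes, 16 were higher, with a median of 1.48, against 10 higher and 1 lower by total reads. The feedback inhibitors Socs1, Usp18 and Socs3 reached log2 ratios of 7.73, 6.22 and 6.13, and Ifngr1, Ifngr2, Il10rb, Jak1 and Pias1 were neither. Nucleic-acid sensors and adaptors were higher for 16 of 28 genes, with a median of 1.47, against 13 higher and 1 lower by total reads. The RNA sensor Ifih1 stood at 5.83, the Z-nucleic-acid sensor Zbp1 at 5.21 and the transcription factor Irf7 at 5.17. Immediate-early transcription factors and related early-response genes were higher for 19 of 29, with a median of 1.40, against 14 higher and 2 lower by total reads. Among them were Arc (6.31), Nr4a3 (5.55), Dusp2 (4.16) and Zfp36 (2.57), whereas Egr2 was lower (-1.88).

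**Figure D3:**
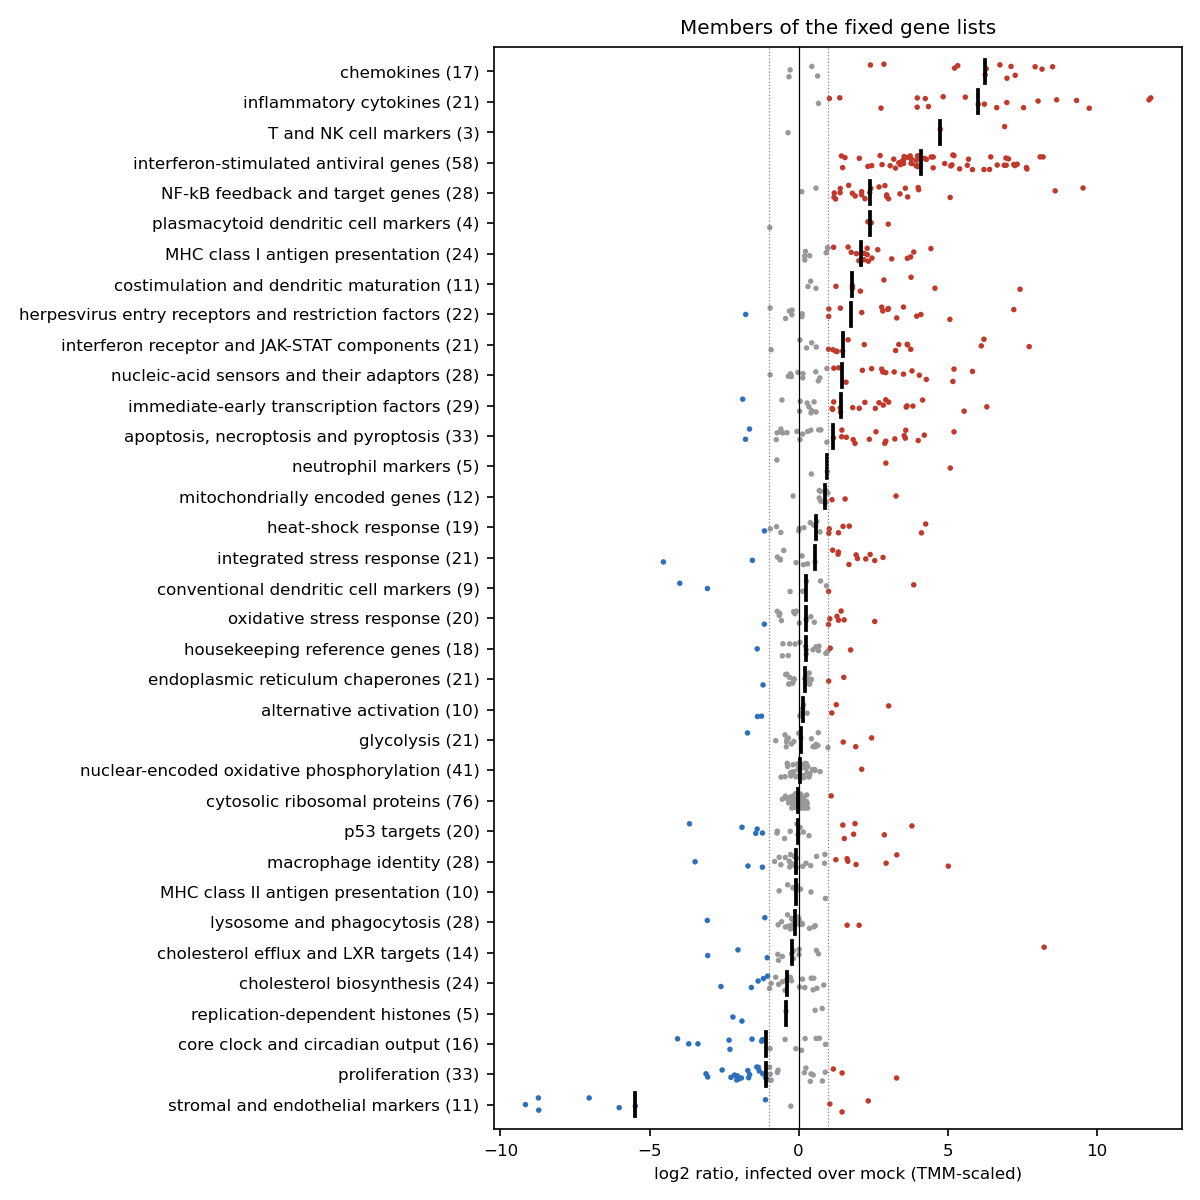
Log2 ratios of the infected to the mock library for every assessed member of the 35 gene lists with at least 3 assessed members, with the number of assessed members in parentheses, black bars at the list medians, and red, blue and grey points for higher, lower and neither. Chemokines (6.26) and inflammatory cytokines (6.02) have the highest medians and stromal and endothelial markers (-5.47) the lowest, and the medians between -0.02 and 0.57 change sign under other scalings.

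Antigen presentation split by class. MHC class I genes were higher for 17 of 24, with a median log2 ratio of 2.11, led by the transactivator Nlrc5 (4.44) and the peptide transporter gene Tap1 (3.86), whose locus overlaps Psmb9. H2-Q7 stood at 3.76, with reads that near-identical H2-Q genes can share. B2m, the most abundant member, had a log2 ratio of 0.98 and was neither. The abundant class I molecule genes H2-K1 (0.97) and H2-D1 (0.20), named after their values were seen, were also neither. None of 10 MHC class II genes was higher or lower, with a median of -0.08, while by total reads 1 was lower (Ifi30), with a median of -0.70, and 2 were lower without the 10 most abundant genes in the totals. H2-Ab1 had a log2 ratio of 0.41, which was -0.20 with scaling by total reads. Costimulation and dendritic maturation genes were higher for 8 of 11, with a median of 1.81, against 7 and 1.19 by total reads. Cd40, a receptor for T cell help, was 172-fold higher (149 to 199.9), and Cd274, which encodes PD-L1, was 13.7-fold higher (13.3 to 14.0). Fscn1, Irf4 and Relb were neither. Cell death genes were higher for 17 of 33, with a median of 1.17, including the inflammasome sensor Nlrp3 (4.22), the caspase 8 regulator Cflar (4.01) and the survival gene Mcl1 (1.17). Casp9 (-1.78) and Nlrp1b (-1.65) were lower. By total reads 13 cell death genes were higher and 8 lower, with a median of 0.55.

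Macrophage identity genes went both ways. Of 28 assessed, 7 were higher, 3 were lower and 18 were neither, with a median log2 ratio of -0.08 (95% interval -0.30 to 0.87). By total reads 6 were higher and 7 lower, and with totals that left out the 10 most abundant genes 4 were higher and 9 lower. The scavenger receptor gene Marco was 32.5-fold higher (26.3 to 40.5) and the Fc receptor gene Fcgr1 was 9.80-fold higher (9.11 to 10.6). The lower members included Cx3cr1 (-3.47) and Fcgr3 (-1.21). Csf1r, the receptor for macrophage colony-stimulating factor, had a log2 ratio of -0.81, and the abundant lysozyme gene Lyz2 had a log2 ratio of -0.27, so both were neither, but Csf1r stood at -1.42 by total reads. The list median lay at percentile 0.365 among lists matched on mean expression and 15.8 among lists matched on mock expression. Lysosome and phagocytosis genes were neither for 24 of 28, with a median of -0.12, and 5 were lower by total reads. The receptors for apoptotic cells Axl (2.03) and Mertk (1.63) were higher, and Tfeb (-3.06), a regulator of lysosomal genes, and Atp6v0d2 (-1.13) were lower. Gpnmb, the most abundant gene of the mock library, had a log2 ratio of -0.28. Of 10 alternative activation genes, Klf4 (3.02), Socs2 (1.26) and Tgm2 (1.11) were higher and Clec7a (-1.24) and Vegfa (-1.38) were lower. The median of that list was 0.15, and -0.47 with scaling by total reads, where 1 was higher and 2 were lower.

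Markers of other cell types were mixed, and most of these lists had few assessed members. Among 9 conventional dendritic cell markers, Xcr1 (3.86) and Irf8 (1.01) were higher, and Clec9a (-3.99) and Batf3 (-3.06) were lower, with a median of 0.26 that became -0.36, with 1 higher and 2 lower, with scaling by total reads. Sirpa (1741 mock and 1428 infected CPM) and Itgax (856 and 942 CPM, named after its values were seen) were abundant and neither. The list held 0.361% of mock reads and 0.232% of infected reads, and the libraries do not show which cells these reads came from. Plasmacytoid dendritic cell markers had a median of 2.38, with Ccr9 (3.01), Tcf4 (2.44) and Bst2 (2.32) higher and Runx2 (-0.97) neither. Runx2 was lower by total reads, and with no expression minimum the median was 0.49 over 7 genes, with 3 higher and 1 lower. Neutrophil markers had a median of 0.96, with Lcn2 (5.09) and S100a8 (2.93) higher and Mmp8, Csf3r and Mmp9 neither. By total reads Mmp8 was lower (-1.35) and the median was 0.34. Of the T and NK cell markers, Klrk1 had 2 mock and 192 infected reads and Lck had 4 and 86, both higher, while Cd4 had 56 and 35 and was neither, and the median was 4.75, which was 2.12 with a pseudocount of 1 CPM. The mast cell gene Hdc, which makes histamine, was higher (6.41), and Gata2 was neither, with a median over these 2 of 3.44 that was 2.13 with the pseudocount. The eosinophil genes Siglecf (-0.78) and Ccr3 (-0.50) were neither, but both were lower by total reads, with a median of -1.26. The megakaryocyte gene Pf4 was neither. No B cell marker reached the expression minimum, with 62 mock and 28 infected reads over 7 genes.

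Stromal and endothelial markers were the list with the lowest median. Of 11 assessed, 7 were lower, 3 were higher and 1 was neither. Col1a1 (-9.16), Sparc (-8.73) and Col1a2 (-8.72) were joined by Col3a1, Acta2, Dcn and Cxcl12, chosen after their values were seen. The median of -5.47 (95% interval -8.73 to 1.46) was set by Dcn, which had 167 mock reads and 0 infected reads, so it depends on the floor of 3 reads. The median was negative under every setting but ranged widely, from -1.68 with no expression minimum, -2.84 with a pseudocount and -3.10 after thinning to -7.02 at a minimum of 5 CPM. Pdgfrb (2.34), Kdr (1.46) and Cdh5 (1.05) were higher and Pdgfra (-0.26) was neither, and by total reads only Pdgfrb of these was still higher. The whole list made up 0.0611% of mock reads and 0.00791% of infected reads. These markers and a further stromal list, written after the values of these markers but before its own were read, held 24 of the 1759 lower genes.

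Proliferation and sterol genes were lower in part. Of 33 proliferation genes, 18 were lower and 3 were higher, with a median log2 ratio of -1.11 (95% interval -1.68 to -0.69) and a percentile of 0.165. By total reads 23 were lower and 1 was higher, with a median of -1.73, and at a minimum of 5 CPM on the mean of both libraries 5 of 15 were lower, with a median of -0.69. The mitotic kinesin gene Kif20a (-3.11) and the kinase gene Aurkb (-3.05) were lower, whereas the cyclin gene Ccne1 (3.28), Mki67 (1.46) and Tpx2 (1.17) were higher, of which only Ccne1 was still higher by total reads. Of 5 assessed histone genes, Hist2h2be (-2.20) and Hist1h1c (-1.90) were lower, with a list median of -0.42 that was 0.79 with no expression minimum and 0.11 in thinned libraries, and by total reads 3 were lower. Cholesterol biosynthesis had 0 higher and 5 lower genes of 24, with a median of -0.39 (95% interval -0.92 to 0.13) and a percentile of 1.03. By total reads 12 were lower, with a median of -1.01. The lower members were Dhcr7 (-2.60), Mvd (-1.58), Fdps (-1.36), Lss (-1.18) and Mvk (-1.04). Among 14 cholesterol efflux and LXR target genes, with a median of -0.21, Ch25h was higher, with 7 mock and 1684 infected reads (301-fold, 146 to 750.1). Scd2 (-3.05), Arl4c (-2.03) and Cyp27a1 (-1.05) were lower, and by total reads 6 were lower.

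Most nuclear-encoded metabolic and ribosomal protein genes were neither higher nor lower. Of 21 glycolysis genes, Pfkfb3 (2.45), Hk2 (1.91) and Pfkp (2476 mock and 5580 infected reads) were higher and Pfkfb4 (-1.71) was lower, with a median of 0.08 that was -0.54, with 6 lower, with scaling by total reads. Nuclear-encoded oxidative phosphorylation genes were neither for 40 of 41, with Cycs (2.12) higher and a median of 0.05 that was -0.57, with 3 lower, with scaling by total reads. Cytosolic ribosomal protein genes were neither for 75 of 76, with Rpl24 (1.09) higher and a median of -0.02 that was 0.02 with DESeq2 size factors. With scaling by total reads the median was -0.63, Rpl24 (0.47) was no longer higher and 2 genes were lower. Rpl24 had 108 mock and 184 infected reads, and its locus overlaps Gm28037 on the same strand. Mitochondrially encoded genes had a median of 0.88, with mt-Nd4l (3.27), mt-Atp6 (1.56) and mt-Atp8 (1.12) higher of 12, and by total reads 1 was higher, with a median of 0.26. On the same strand, mt-Nd4l overlaps mt-Nd4, mt-Atp8 overlaps mt-Atp6, and mt-Atp6 also overlaps mt-Co3. The assignment of reads to these higher genes is therefore uncertain. Of 18 housekeeping reference genes, Actb (1.74) and Ywhaz (1.06) were higher, with a median of 0.26 that was -0.36, with 1 higher and 3 lower, with scaling by total reads. Actb was 3.35-fold higher (3.33 to 3.37), with a log2 ratio of 1.13 by total reads. Gapdh had a log2 ratio of 0.48, which was -0.13 by total reads.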

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

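The deposited size factors were tried after the data had been seen, as was leaving out the stromal genes, which takes 24 from the lower genes by construction (1735). With scaling by total reads, 1076 genes were higher and 3731 lower, in place of 1868 and 1759, and the list medians were 3.50 for interferon-stimulated genes, -0.57 for oxidative phosphorylation, -0.63 for ribosomal proteins and -0.69 for macrophage identity, while 9 list medians changed sign, of which heat-shock (-0.078) was the one whose interval had excluded 0. With totals that left out the 10 most abundant genes, the counts were 993 and 4124, and the same medians were 3.40, -0.66, -0.73, -0.79 and, reversed for heat-shock, -0.17, with the same 9 lists changing sign. Both follow from their construction. The higher genes took 42.8% of infected reads against 12.7% of mock reads. The 10 most abundant genes of each library, in contrast, held 17.7% of mock reads and 12.1% of infected reads. A minimum of 5 CPM left no T and NK cell marker, so it gave that list no median, and 997 lower genes, a ratio of 4 left 845 higher and 552 lower, and a whole interval past 2-fold left 1153 lower, as stricter rules applied to fewer genes or larger ratios. All other counts of higher or lower genes stayed within 1.5 times: 1922 and 1687 with DESeq2 size factors, 2390 and 2306 with no expression minimum, 1740 and 1375 with the pseudocount, 1830 and 1800 after thinning, 1872 and 1756 with the deposited size factors, 1583 higher at 5 CPM, and 1593 higher with the whole interval past 2-fold. All 118 called named genes kept their direction under the 8 settings that changed scaling, filter, pseudocount or depth, and between 103 and 118 kept their call. Settings meant for RPKM, FPKM or TPM files were not run because the files hold another unit, and no paired analysis was possible because each group had 1 library, which also left no replicate to leave out. Depth limits the interferon alpha genes and other genes under 1 CPM, whose differences were not assessed.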

Other observations

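The decay estimate was chosen only after the result was seen, and the other tests were fixed before their own values were read. Clock and circadian output genes were lower for 8 of 16, with a median log2 ratio of -1.09. Its 95% interval of -2.33 to 0.22 included 0, and its percentile was 0.07 among lists matched on mean expression. Dbp, an output gene of the clock, had 188 mock and 9 infected reads (16.7-fold lower, 95% interval 8.61 to 37.1), Per3 stood at -3.68 and Npas2 at -3.38, and no member was higher. At a minimum of 5 CPM on the mean of both libraries, which itself left out Dbp, Per3 and Npas2 for their low infected values, the median was -0.09, with 4 of 11 lower. The treatment labels give 6 h of infection for the infected library and untreated for the mock library, without a harvest time for the latter. A difference in time of harvest therefore cannot be told apart from infection. Herpesvirus entry receptors and restriction factors were higher for 14 of 22, with a median of 1.76 (95% interval -0.22 to 3.29), and 11 were higher and 3 lower by total reads. The higher members included the GTPase gene Mx2 (7.22), which is annotated as a polymorphic pseudogene, and the integrin gene Itgb8 (5.07). The antibody receptor gene Trim21 (4.10) and the dNTPase gene Samhd1 (2.82) were also higher. Nectin1, an entry receptor of HSV-1, was the lower member (-1.78), chosen after its value was seen.

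Stress programmes were mixed. Among 20 p53 targets, 6 were higher and 5 lower, with a median of -0.04, against 4 and 8 by total reads: Cdkn1a (3.80) and Plk2 (2.87) were higher, and Sesn1 (-3.66), Phlda3, Gadd45a, Trp53inp1 and Zmat3 were lower. Integrated stress response genes were higher for 10 of 21, with a median of 0.55 that was -0.07, with 7 higher and 6 lower, with scaling by total reads. Ppp1r15a (2.83) and Slc7a11 (2.55) were higher, and Aldh1l2 (-4.53) and Trib3 (-1.55) were lower. Of 21 endoplasmic reticulum chaperone genes, Hspa5 (1.51) and Syvn1 (1.01) were higher and Herpud1 (-1.19) was lower, with a median of 0.21 that was -0.41, with 0 higher and 3 lower, by total reads. Heat-shock genes were higher for 7 of 19, with Hspa1a at 4.26, Hspa1b at 4.12 and Stip1 at 1.70, Hspb1 (-1.15) lower, and a median of 0.57 that was -0.08, with 3 higher and 5 lower of 20, by total reads. Hspa1a and Hspa1b are near-identical, so the split of reads between them is uncertain. Oxidative stress genes were higher for 7 of 20, including Txnrd1 (1.53) and Sqstm1 (1.43), with Gsta3 (-1.15) lower and a median of 0.26 that was -0.36, with 1 higher and 5 lower, by total reads. Phlda3, Gadd45a, Trp53inp1, Zmat3, Trib3, Hspb1 and Gsta3 were named after their values were seen.

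Matrix genes such as Col1a1 (212 mock CPM, 0.370 infected CPM) were almost missing from the infected library, and a second list of stromal genes, none of them in the other lists, was written before its values were read. Its 27 assessed members had a median log2 ratio of -3.58 (95% interval -5.87 to -0.20), with 17 lower, 5 higher and 5 neither, so 10 of them were expressed in the infected library with no 2-fold loss. That median lay at percentile 0 among lists matched on mock expression, which argues against a general decline of genes at that level. The second list as a whole held 24863 mock and 24745 infected reads, or 0.114% and 0.0923% of all reads. Its total therefore did not drop as its median did. Fewer stromal cells in the infected culture may explain the matrix genes, and the labels name no sort that would remove such cells. Vcan (4.75), Fap (2.65), Lox (2.01) and Pdgfrb (2.34), chosen after their values were seen, were higher, which such a loss alone leaves unexplained. The libraries do not show which cells these reads came from, so these genes cannot decide whether stromal cells were lost. Decay after infection remains open: with transcription stopped at 0 h, Col1a1 would need a half-life of about 39.3 minutes (at most 44.0 at the lower 95% limit of its fold), and no decay data were used here.

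The 1759 lower genes had a higher transcript GC content (median 52.2%) than the higher genes (47.5%), and across genes, which are not independent replicates, GC content and log2 ratio had a Spearman rho of -0.23. Removing the GC trend left 1586 genes at least 2-fold lower (0.903 times the 1757 with a known GC content, 1452 of them in common), and removing the length trend left 1678 (0.955 times, 1632 in common). Neither bias therefore accounts for the lower genes as a whole. Lower expression of FOXO targets was tested because Sesn1 was lower, with a list written before its values were read. Its 17 assessed genes (Klf2 is also an immediate-early gene) had a median of -0.01 (95% interval -0.91 to 1.44) at percentile 45.27 among lists matched on mock expression, with 6 higher and 3 lower. The prediction written for lower FOXO targets, a median below percentile 2.5, was therefore not met. Members went both ways and the interval spans lower and higher medians, so the question stays open. An effect of infection itself is also open, untested without replicates.

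Of 3094 genes with under 1 CPM in the mock library, 779 were higher in the infected library. Such a gene could be called only with an infected value above 1 CPM, so none could be lower. The choice of genes by a low mock value thus itself favours higher calls. Transcription running on from an upstream neighbour is a further candidate explanation. Of 262 such genes with an expressed same-strand neighbour within 10 kb upstream only, 81 (30.9%) were higher, against 46 of 159 (28.9%) with such a neighbour downstream only and 24.4% with neither. The odds ratio was 1.10 (95% interval 0.70 to 1.74). The interval includes both 1 and 1.5, so read-through and its absence cannot be told apart with these gene numbers.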
